A study of Mus musculus with 28 samples.

How the data were processed

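The series holds 28 samples of mouse satellite cells, the stem cells of skeletal muscle, from WT animals on a C57Bl/6 background and from SIRT1mKO animals, in which Cre expressed from a Pax7 knock-in removes the floxed exon 4 of Sirt1, per the labels. Of these samples, 18 are polyA RNA-seq libraries, and the other 10 (3 ChIP samples of H4K16ac, 4 of SIRT1 and 3 inputs) were not analysed here. The RNA-seq groups hold 5 WT_FI, 3 KO_FI, 4 WT_Cul, 2 KO_Cul, 2 WT_Diff and 2 KO_Diff libraries. FI stands for freshly isolated quiescent cells sorted by FACS, Cul for proliferating cells in medium with 20% fetal bovine serum and 12.5 ng/ml bFGF, and Diff for cells kept for 24 hours in medium with 2% horse serum, per the labels. KO stands for SIRT1mKO throughout.

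The deposited data are 4 tables written by Cuffdiff per gene and library, per the file headers: KO_FI against WT_FI (3 against 3 libraries), KO_Cul against WT_Cul (2 against 2), KO_Diff against WT_Diff (2 against 2) and WT_Cul against WT_FI (2 against 2). The deposited raw fragments are estimated counts per gene, per the file headers, and 1.42% to 8.18% of the values above 0 in a library were not whole at a tolerance of 0.01. The deposited FPKM values were scaled by the authors within each table, per the file headers. The submitters' processing notes name Bowtie, TopHat, SICER, Cuffdiff and the genome build mm9, without roles, and their versions are not given in the sources used here. Each table lists 22552 genes by symbol, without positions, so no coordinates are printed. The columns name the condition and an index from 0 within the table, and not the replicate number of the labels, so a library is named here by its group and its index. The letters for the proliferating state in the tables were matched to that group because the other conditions were accounted for. The 4 tables hold 18 distinct libraries. Within a group, the lowest chi-square per degree of freedom between libraries was 27.98, so none was a copy of another within sampling noise. Columns of per-sample values left unused numbered 0.

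Genes whose status in a table was not OK in every library were left out of that table, 22 in the FI table, 12 in Cul, 19 in Diff and 27 in the table of WT states. Among them were genes too abundant for the authors' run to estimate, such as Fos, Jun, Egr1, Hspa1a and Hspa1b in the FI table. Results for some genes are not reported here. Estimated fragments were rounded to whole numbers. Each comparison was fitted within its own table with edgeR's quasi-likelihood F test (robust, TMM factors, filterByExpr), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are CPM, counts relative to TMM-scaled library sizes, and are comparable only within a table. Fold changes are log2, KO against WT or Cul against FI, with the standard error (SE) of the fit. Means are given with SD. Where all libraries of a group were at 0, the fold is a lower bound against a floor of 3 fragments per library, which covers counting error only. The counting is not stated to use strand, and fragments of near-identical genes may be divided between copies, so values of such genes are uncertain.

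Before the data were examined, the tests, the libraries of each fit, 26 gene lists, the rule for named genes and most alternatives were fixed. The lists were quiescent satellite cell, myogenic commitment, muscle differentiation and contraction, mature myofibre, G1/S and DNA replication, G2/M, p53 targets, glycolysis, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, sirtuins and NAD metabolism, H4K16 acetyltransferase complexes, Notch pathway, immediate early and heat shock, NF-kB targets, interferon response, autophagy and lysosome, ribosome biogenesis, and markers of fibroblasts (with fibro-adipogenic progenitors), endothelial cells, macrophages and leukocytes, lymphocytes, pericytes and smooth muscle, Schwann cells and erythroid cells. The quiescent and Notch lists share Hes1, Hey1, Heyl and Notch3, and the myogenic and muscle lists share Myog. Some cell type markers, such as Cd34, are also expressed by satellite cells. Lists with at least 3 measured genes were tested with limma's camera (preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. The named genes are Sirt1, then up to 8 genes in each direction with the largest fold change among those that passed, that did not overlap between groups and that had at least 5 CPM in the higher group. Where fewer than 16 passed, the smallest p-values among non-overlapping genes filled the list, and their values are given without a call. Up to 4 members of each described list with the smallest p, and Pax7, Myod1, Myf5 and Myog, were also named, and predicted genes were passed over. Genes named with the block or over all 7 pairs were chosen after their values were seen.

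The difference of the KO effect between states was tested with contrasts over the 3 joined KO tables. Activation signatures were the 200 genes with the largest increase and the 200 with the largest decrease from WT_FI to WT_Cul among genes that passed, and differentiation signatures were made in the same way from WT_Diff against WT_Cul, across separately processed tables, where the signature of decreasing genes held only 91 genes (88 of them measured in FI). No library served both a signature and the comparison it was tested in. Alternatives were RLE size factors, no low-count filter, DESeq2, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a minimum FPKM of 1, a minimum absolute log2 change of 1, leaving out each library, a fit over all 18 libraries, all WT libraries, camera with an estimated correlation, fry, and signatures of 100 and 500 genes.

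The libraries' deviations from their group means were correlated within each index of the FI table (0.866, 0.683 and 0.584 for indices 0, 1 and 2). With all 3 above 0, the index was taken to pair the FI libraries. Values from a fit with this index as a replicate block are given where they change an FI call. The 3 correlations are not independent, since deviations from a group mean sum to 0, and index 0 stood apart in both genotypes. Its chi-square per degree of freedom was 548.4 and 350.5 in WT_FI and 472.7 and 428.2 in KO_FI. Between indices 1 and 2 it was 112.4 and 27.98. Correlations between different indices were not computed, so a pairing of indices 1 and 2 is not shown. The pairing comes from the index in the table and not from the labels. The block by table index, the fit without the FI libraries of index 0, and the other tables' WT libraries were alternatives chosen after seeing the data.

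Depth was 28010691 to 65324684 fragments per library in the FI table, 75674366 to 82590642 in Cul, 71858446 to 82825550 in Diff and 24254119 to 31643216 in the table of WT states. The procedures were tested on simulated counts with 200 changed genes, drawn from the real means and depths. For FI, over 14943 genes without pair effects, the edgeR fit recovered 12.7% of 2-fold and 70.4% of 4-fold changes, with 4.65% of its calls false, and DESeq2 recovered 42.2% and 86.7%, with 36.3% false. With pair effects, edgeR recovered 5.71% and 73.7% without a block (15111 genes, 0% of calls false) and 71.4% and 92.6% with the replicate block (15352 genes, 15.5% false). DESeq2 then recovered 54.3% and 93.7% without a block (0.68% false) and 78.1% and 94.7% with it (19.2% false). For Cul, over 13693 genes without pair effects, edgeR recovered 3.03% of 2-fold and 75.2% of 4-fold changes, with 14.1% of its calls false. With pair effects it recovered 0% of either size in Cul (13768 genes), so that 0 genes called there do not show that few changed. For Diff, over 14161 genes, edgeR recovered 0% of either size, and for the WT states, over 14431 genes, 0% of 2-fold and 1.01% of 4-fold changes. Of 100 unchanged lists per comparison, camera gave an unadjusted p under 0.05 for between 1 and 7 with the preset correlation and for 0 with an estimated correlation. These lists held random genes that were drawn independently. The simulation therefore does not show the error rate for lists whose genes move together. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. The annotation GRCm38.p6 was used only for which genes neighbour each other.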

Results

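Transcripts were measured by polyA RNA-seq in satellite cells of WT and SIRT1mKO (KO) mice in 3 states: freshly isolated quiescent cells (FI), proliferating cells in culture (Cul) and cells after 24 hours in differentiation medium (Diff). SIRT1 is a protein deacetylase that depends on NAD. The libraries numbered 5 in WT_FI, 3 in KO_FI, 4 in WT_Cul, 2 in KO_Cul, 2 in WT_Diff and 2 in KO_Diff, and lay in 4 separately processed tables. Depth was 28010691 to 65324684 fragments per library in the FI table, 75674366 to 82590642 in the Cul table, 71858446 to 82825550 in the Diff table and 24254119 to 31643216 in the table of WT states. The labels do not say that libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. All adjusted p-values for genes are from edgeR's quasi-likelihood test and those for lists from limma's camera, each with Benjamini-Hochberg adjustment.

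Sirt1 itself was present in every library. A total per gene does not set exon 4 apart from the other exons, so these values cannot check the deletion. In the FI table, Sirt1 was at 81.4, 50.6 and 47.4 CPM in WT_FI and at 63.4, 37.6 and 44.3 CPM in KO_FI (indices 0, 1 and 2). The means were 59.8 ± 18.8 and 48.5 ± 13.3 CPM (SD, n = 3 each). In Cul, Sirt1 was at 62.2 and 66.8 CPM in WT and at 33.8 and 46.9 CPM in KO (64.5 ± 3.28 and 40.4 ± 9.24, n = 2 each). In Diff it was at 52.1 and 28.2 CPM in WT and at 41.4 and 28.8 CPM in KO (40.1 ± 16.9 and 35.1 ± 8.86, n = 2 each). The log2 differences of −0.30, −0.68 and −0.19 did not pass the test (adjusted p = 1.00 in each), and that in Diff turned to 0.33 without WT_Diff index 0 and to 0.062 without KO_Diff index 1. In the table of WT states, Sirt1 was at 63.7 and 90.8 CPM in WT_FI and at 54.5 and 84.6 CPM in WT_Cul, a log2 difference of −0.15 (adjusted p = 0.796) that turned to 0.13 without WT_FI index 1 and to 0.087 without WT_Cul index 0.

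**Figure D1:**
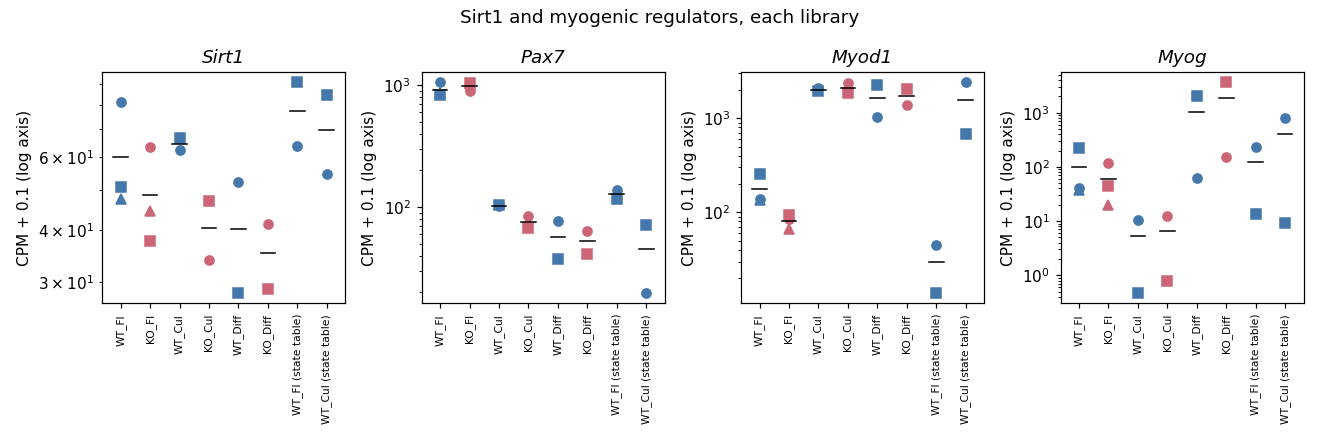
Sirt1, Pax7, Myod1 and Myog in each library, as CPM + 0.1 on a log axis, for KO and WT groups and for both WT states (state table), with circles for index 0, squares for index 1, triangles for index 2, blue for WT, red for KO and a horizontal line at the arithmetic mean. Myod1 lies at a mean of 29.4 CPM in WT_FI and 1545 CPM in WT_Cul of the state table, while the KO and WT libraries of each state overlap for Myog.

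KO_FI was compared with WT_FI to ask what the loss of SIRT1 activity alters in quiescent satellite cells. The list of G1/S genes, which prepare and carry out DNA replication, fell with a median log2 change of −0.50 and estimates below 0 for 19 of 19 genes, among them Cdc6 (−1.13), Mcm2 (−0.69), Mcm5 (−0.68) and Mcm3 (−0.51). The G2/M list, which drives mitosis, fell with a median of −0.86 and 21 of 21 estimates below 0, among them Ube2c (−1.15), Birc5 (−1.13), Nusap1 (−0.93) and Cenpe (−0.90). The list of immediate early transcription factors and heat shock proteins fell (median −0.60, 19 of 19 below 0), with Fosb at −0.73, Klf4 and Nr4a1 at −0.62 each and Jund at −0.57, and the abundant members Fos, Jun, Egr1, Hspa1a and Hspa1b were left out of this table. The list of oxidative phosphorylation, the mitochondrial respiratory chain, fell less (median −0.24, 24 of 24 below 0), with Cox5a at −0.44, Cox7a2 at −0.29, Sdhb at −0.24 and Ndufa9 at −0.17. The list of interferon response genes, which act in antiviral defence, rose (median 0.20, 12 of 17 above 0), with Mx1 at 0.62, Oasl2 at 0.53, Dhx58 at 0.35 and Ddx58 at 0.20.

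These 5 of 26 lists passed camera with adjusted p = 3.49e-09 (G1/S), 1.28e-07 (G2/M), 2.26e-06 (immediate early), 0.000695 (oxidative phosphorylation) and 0.0131 (interferon). Each had adjusted p = 0.788 with an estimated correlation. Of their members, 0 passed over all genes or adjusted over the list alone. The mean log2 CPM of the G2/M list was 2.80, 4.29 and 3.05 in WT_FI and 3.06, 2.11 and 2.65 in KO_FI (indices 0, 1 and 2), so that it was higher in KO within index 0. The G1/S list was at 3.94, 4.49 and 3.96 in WT_FI and 3.80, 3.41 and 3.62 in KO_FI. The immediate early list, over the 18 genes kept when all libraries were joined, was at 10.39, 10.49 and 10.25 in WT_FI. In KO_FI it was at 10.32, 9.42 and 9.42, nearly level within index 0. The other 21 lists, including quiescence genes and all markers of other cell types, did not pass (lowest adjusted p = 0.0914, for the tricarboxylic acid cycle). For fatty acid oxidation, sirtuins and Schwann cells, the signs of the test, the median and the mean differed. Adjusted over the list alone, 1 member passed in each of 3 lists, the quiescence gene Sdc3 (0.91), the muscle calcium channel Ryr1 (1.03) and the skeletal myosin kinase Mylk2 (1.48), and 0 in all others. With the replicate block these 3 were joined, all lower in KO_FI, by Cd34 (−0.56) of the quiescence list, Myod1 (−1.05) of myogenic commitment, the NF-kB targets Tnfaip3 (−0.84) and Birc3 (−0.64) and the autophagy gene Gabarapl1 (−0.50). The lymphocyte markers Cd79a (−0.86) and Cd79b (−1.21) were also lower and passed over their list alone with the block. Leaving out WT_FI index 1 ended the calls of oxidative phosphorylation and interferon (adjusted p = 0.298 for both), leaving out KO_FI index 0 did so too (0.0534 and 0.187), and leaving out WT_FI index 0 ended that of interferon (0.0584), as did leaving out both libraries of index 0 (0.184). With the replicate block, 8 lists passed, the further 3 being NF-kB targets (Down, adjusted p = 0.0241), p53 targets (Down, 0.0483) and endothelial markers (Up, 0.0483), each at adjusted p = 0.834 with an estimated correlation.

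Among single genes, the smallest p-value in FI belonged to Elovl4, an elongase of very long chain fatty acids, at 27.9 ± 5.14 CPM in WT_FI and 3.18 ± 0.541 CPM in KO_FI (log2 −3.13, SE 0.22, adjusted p = 0.0894), which did not pass. Levels were also lower in KO_FI for the calcium channel Ryr3 (193 ± 69.3 and 21.0 ± 6.25 CPM, log2 −3.20), the heparanase Hpse (13.4 and 1.94 CPM, −2.78), the potassium channel subunit Kcne4 (255 ± 31.5 and 70.2 ± 13.9 CPM, −1.86) and the protease inhibitor Serpini1 (76.7 and 30.8 CPM, −1.32). They were higher in KO_FI for doublecortin, Dcx (2.54 and 20.7 CPM, 3.02), for Mylk2 (42.4 ± 8.36 and 118 ± 6.26 CPM, 1.48), Vstm2a (1.56), Arhgap22 (1.47), Wisp2 (1.20) and Cyb561 (1.10). Bsnd (−2.31), Iqch (−2.17), Pof1b (−1.78), Fgf12 (−1.68) and Tmem229a (−0.99) complete the 16 genes with the smallest p-values, and their adjusted p ranged up to 0.391. Of the regulators of satellite cells, Pax7 was at 918 ± 123 and 994 ± 79.1 CPM (log2 0.12), Myod1 at 175 ± 66.5 and 81.6 ± 14.3 CPM (−1.10, SE 0.29, adjusted p = 0.822), Myf5 at 306 and 288 CPM (−0.086) and Myog at 101 ± 108 and 60.7 ± 50.3 CPM (−0.73). The sign for Myog turned to 0.64 without WT_FI index 1. By edgeR, 0 of 15146 genes passed and 621 had an unadjusted p under 0.05 (757 by chance), against 117 that passed in DESeq2 (67 higher, 50 lower) and 0 in limma on log2(FPKM + 1). Groups did not overlap for 1397 genes (9.22%, with 10% by chance). With the replicate block 3 genes passed in edgeR, all lower in KO_FI at adjusted p = 0.0473: Hpse (−2.78), the atypical GTPase Rhoh (58.8 and 13.0 CPM, −2.26) and the muscle actin regulator Lmod2 (82.5 and 20.1 CPM, −2.09). DESeq2 with the block gave 255 (95 higher, 160 lower).

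KO_Cul was compared with WT_Cul to ask the same of proliferating cells. The list of fibroblast genes, which encode mostly collagens and other matrix proteins, rose in KO_Cul with a median of 1.20 and estimates above 0 for 11 of 12 genes, among them Col1a2 (1.93), Mfap5 (1.87), Pdgfra (1.78) and Col1a1 (1.74). Some of these levels were low, with Pdgfra at 0.256 and 0.828 CPM in WT_Cul and at 0.552 and 3.18 CPM in KO_Cul (indices 0 and 1). The pericyte and smooth muscle list rose with a median of 0.62 and 5 of 5 estimates above 0, with the growth factor receptor Pdgfrb at 1.33 and the actin-binding protein Tagln at 0.97. Enzymes of glycolysis rose by less, with a median of 0.20 and 15 of 19 above 0, among them Pfkl (0.37), Tpi1 (0.34), Pfkm (0.31) and Hk1 (0.28). The adjusted p was 0.00671 for fibroblast genes and 0.0393 for each of the other two, and adjusted p = 0.818, 0.818 and 0.863 with an estimated correlation for fibroblast, pericyte and glycolysis. Of the members of any list, 0 passed over all genes and 0 adjusted over the list alone. The remaining 21 of 24 lists tested did not pass, G1/S and G2/M among them, and lymphocyte and erythroid markers had too few measured genes. For G2/M, p53 and Notch genes the signs of test, median and mean differed. The fibroblast call ended without KO_Cul index 1 (adjusted p = 0.213), that of glycolysis without WT_Cul index 1 (0.905) or KO_Cul index 0 (0.608), and that of pericytes without WT_Cul index 0 (0.418), WT_Cul index 1 (0.264) or KO_Cul index 1 (0.924). Libraries of the same index in both genotypes were alike in Xist, the RNA of the inactive X chromosome, at 1.06 (WT) and 0.359 (KO) CPM for index 0 and at 2287 (WT) and 1217 (KO) CPM for index 1. Ddx3y, a gene of the Y chromosome, was at 88.7 (WT) and 36.5 (KO) CPM for index 0 and at 32.4 and 32.6 CPM for index 1. Xist alone therefore does not show that these libraries were matched in sex.

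By edgeR, 0 of 13963 genes passed in Cul, with 112 at an unadjusted p under 0.05 (698 by chance), 3 genes lower in KO by DESeq2 and 0 by limma on log2(FPKM + 1). Elovl4 again had the smallest p-value, at 20.2 ± 0.0211 CPM in WT_Cul and 5.24 ± 0.75 CPM in KO_Cul (log2 −1.95, SE 0.26, adjusted p = 1.00). Levels were lower in KO_Cul for Cdh6 (−1.88), the potassium channel Kcnq5 (−1.87), Prrg4 (−1.78), Sned1 (−1.35), the cell cycle kinase Cdk6 (20.4 and 9.38 CPM, −1.12), Zbtb20 (−1.11), the prostaglandin reductase Ptgr1 (416 and 235 CPM, −0.83) and connexin 43, Gja1 (164 and 95.7 CPM, −0.78). They were higher for Col1a1 (1.74 and 5.82 CPM), Hic1 (1.13), Col16a1 (1.11), Npcd (0.98), Rsc1a1 (0.97) and the collagen receptor Mrc2 (0.81), and none of these genes passed. Pax7 was at 103 and 75.6 CPM (−0.44), Myf5 at 109 and 72.3 CPM (−0.60), and Myod1 (0.067) and Myog (0.27) turned to −0.15 and −2.94 without KO_Cul index 0, and Myog to −0.68 without WT_Cul index 1.

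KO_Diff was compared with WT_Diff to ask how the loss bears on differentiation. Contractile and other muscle genes rose as a list in KO_Diff, with a median of 0.96 and 34 of 34 estimates above 0, among them slow myosin Myh7 (2.62), nebulin Neb (2.14), Klhl31 (1.24) and dystrophin Dmd (0.84). The list of myogenic commitment rose (median 0.40, 13 of 15 above 0), with Mef2a at 1.20, Mef2d at 0.68 and Cdh15 at 0.53. Lists named for quiescence (median 0.33, 12 of 18 above 0) and for the Notch pathway, a signal that holds satellite cells undifferentiated (0.56, 9 of 11), rose as well, with the cell cycle inhibitor Cdkn1c at 3.08, Heyl at 1.87, Nrarp at 1.61, Notch3 at 1.31 and Notch1 at 0.58. Markers of pericytes (1.23, 6 of 6; Abcc9 2.35, Pdgfrb 2.07, Tagln 0.95), of fibroblasts (0.44, 12 of 14; Col1a1 2.83, Col1a2 2.46) and of endothelial cells (1.09, 9 of 12) rose too, the endothelial genes from levels as low as 0.203 CPM for Ptprb and 0.0341 CPM for Flt1 in WT_Diff, to 0.620 and 0.249 CPM.

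The 7 lists passed with adjusted p = 7.29e-08 (endothelial), 0.000264 (Notch), 0.000333 (pericyte), 0.00197 (fibroblast), 0.0071 (muscle), 0.025 (quiescent) and 0.0423 (myogenic). In the same order these were adjusted p = 0.739, 0.739, 0.905, 0.739, 0.962, 0.739 and 0.962 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 2 did, Col1a1 and Col1a2. The remaining 17 of 24 lists did not pass, mature myofibre genes (median 1.04, adjusted p = 0.186) and G1/S genes among them, and the signs of test, median and mean differed for G2/M, p53 and leukocyte genes. The muscle list moved far more between indices than between genotypes. Embryonic myosin Myh3 was at 0.945 CPM (WT) and 4.72 CPM (KO) for index 0 and at 612 (WT) and 3933 (KO) CPM for index 1. Skeletal actin Acta1 was at 46.0 and 105 CPM for index 0 and at 5376 and 10330 CPM for index 1, and creatine kinase Ckm at 0.171 and 0.884 CPM, then 86.1 and 347 CPM. Xist was at 1234 and 786 CPM for index 0 and at 0.323 and 0.144 CPM for index 1, each index holding 1 library per genotype. Within indices 0 and 1 the median KO minus WT difference of the muscle list was 1.24 and 1.00, with 33 of 34 genes higher in KO in both. Without WT_Diff index 0 (adjusted p = 0.0252) or KO_Diff index 1 (5.02e-08), the muscle list turned to Down, where WT_Diff holds the larger share of index 1. In these fits the list of myogenic commitment did not pass (0.776 and 0.464), nor did the pericyte list (0.663 and 0.464). The estimates of Myh7 (−3.44), Neb (−1.25), Mef2d (−0.21) and Cdkn1c (−0.018) turned without KO_Diff index 1. The fibroblast call ended without WT_Diff index 0 (0.194) or KO_Diff index 0 (0.922), the quiescent call without WT_Diff index 0 (0.082), WT_Diff index 1 (0.351) or KO_Diff index 0 (0.3), and the Notch call without WT_Diff index 1 (0.0774).

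**Figure D2:**
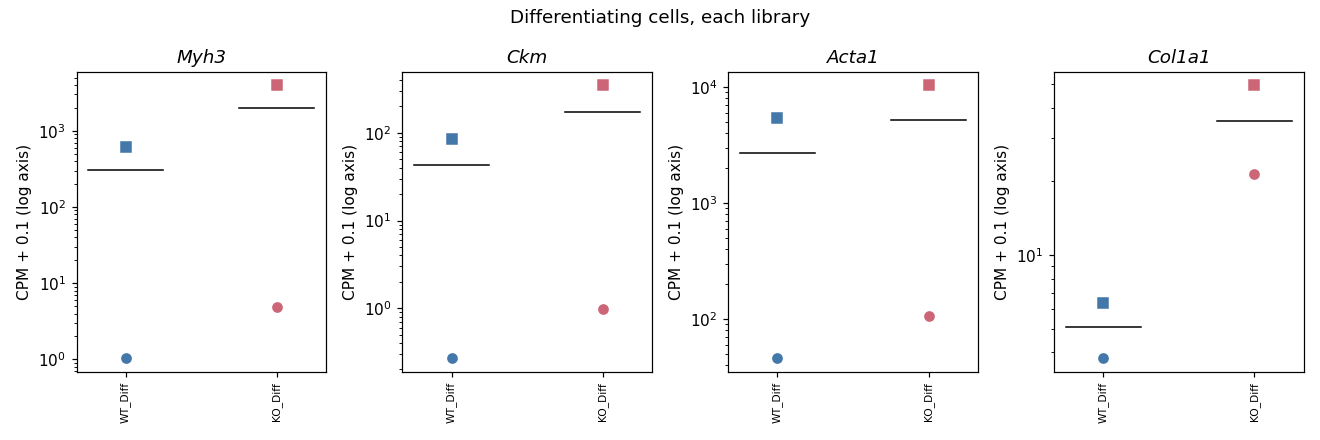
Myh3, Ckm, Acta1 and Col1a1 in each WT_Diff and KO_Diff library, as CPM + 0.1 on a log axis, with circles for index 0, squares for index 1 and a horizontal line at the arithmetic mean of each group. Within each index the KO library lies above the WT library for all 4 genes, and for Myh3 index 1 (612 and 3933 CPM) lies far above index 0 (0.945 and 4.72 CPM).

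By edgeR, 0 of 14482 genes passed in Diff, with 27 at an unadjusted p under 0.05 (724 by chance), and 0 passed by DESeq2 or by limma. In simulated Diff counts this edgeR fit recovered 0% of changes of either size, so 0 calls do not show that few genes changed. With the table index as a block, chosen after seeing the data, edgeR called 147 genes and DESeq2 99, as described further below. The values that follow are from the fit without a block. The fibrillar collagen chains led by p-value: Col1a2 was at 30.6 ± 11.1 CPM in WT_Diff and 169 ± 81.6 CPM in KO_Diff (2.46, SE 0.55), and Col1a1 at 3.70 and 6.25 CPM in WT and 21.4 and 49.2 CPM in KO (2.83, SE 0.63). Levels were also higher in KO_Diff for palladin, Palld (2.09), Atp8b1 (2.06), the splicing factor Rbfox1 (1.75), thrombospondin Thbs1 (72.5 and 237 CPM, 1.71), the collagen Col6a2 (13.1 and 34.2 CPM, 1.38), the metalloproteinase inhibitor Timp3 (1.35), Notch3 (43.4 and 108 CPM), Gbp9 (1.20) and Apeg3 (1.19), which is uncertain because it is antisense to Peg3. They were lower for alcohol dehydrogenase Adh1 (5.31 and 0.997 CPM, −2.41), Elovl4 (16.2 and 4.77 CPM, −1.76), the glutathione transferase Gsta1 (17.1 and 6.05 CPM, −1.50), Ptgr1 (709 and 301 CPM, −1.24) and the carbonyl reductase Cbr3 (−1.03). All 16 had adjusted p = 1.00, as had Pax7 (−0.13), Myod1 (0.063), Myf5 (−0.041) and Myog (0.86). Their signs turned without WT_Diff index 0, to 0.49 for Pax7, −0.38 for Myod1, 0.032 for Myf5 and −0.089 for Myog, and likewise without KO_Diff index 1 (0.17, −0.21 and −2.74 for Pax7, Myod1 and Myog) or KO_Diff index 0 (0.052 for Myf5).

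WT_Cul was compared with WT_FI to ask what activation and growth in culture change in WT cells. Cell cycle genes rose throughout, with 19 of 19 G1/S genes and 21 of 21 G2/M genes higher in WT_Cul. Rrm2, a subunit of ribonucleotide reductase, went from 15.0 to 794 CPM (log2 5.73), and Mcm5 (4.00) and Mcm3 (3.77) rose with it, as did the mitotic genes Ccnb1 (5.40), Kif20a (4.40), Bub1 (4.36) and Bub1b (3.37). All 17 ribosome biogenesis genes rose, among them Wdr12 (3.19) and Rrp9 (3.05). The call of Bop1 ended without WT_FI index 1 (2.48, adjusted p = 0.0729). The myogenic regulator Myod1 rose from 29.4 ± 22.0 to 1545 CPM (5.71, SE 1.01, adjusted p = 0.0190). Of the 23 immediate early and heat shock genes 17 fell and 0 rose, with Fos at 6770 and 74.2 CPM (−6.51), Fosb at −7.21, Socs3 at −6.06 and Zfp36 at −5.73. The medians were 3.43 for G1/S, 4.02 for G2/M, 2.44 for ribosome biogenesis and −3.32 for immediate early genes, with adjusted p = 1.32e-09, 1.32e-09, 5.16e-08 and 1.32e-09. These became adjusted p = 0.422, 0.475, 0.324 and 0.324 with an estimated correlation. Adjusted over the list alone, 19, 21, 17 and 20 members passed.

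Genes of quiescence and of Notch signalling fell. Of 18 quiescence genes 8 were lower and 0 higher (9 lower adjusted over the list alone; median −1.61, adjusted p = 0.00193), among them the cell cycle inhibitor Cdkn1c (−5.33), Notch3 (−5.18), the calcitonin receptor Calcr (−4.52) and Heyl (−3.08). Of 11 Notch genes 6 were lower (7 adjusted over the list alone; median −2.04, adjusted p = 0.00143), among them Nrarp (−5.87), Hey2 (−5.43) and Dtx4 (−3.24). Of 16 interferon genes 12 were lower (14 adjusted over the list alone; median −3.07, adjusted p = 5.55e-06), among them Mx2 (−5.37) and Irf7 (−4.20). Each of these lists had adjusted p = 0.422 with an estimated correlation. Pax7, which marks satellite cells, was at 127 ± 15.0 and 45.1 ± 36.0 CPM (−1.49, adjusted p = 0.140), Myf5 at 66.2 and 160 CPM (1.28, adjusted p = 0.0875) and Myog at 1.74 (adjusted p = 0.548), and these did not pass. Over other WT libraries Myf5 changed sign, at −0.49 with all of them and −1.11 in those of the other tables, where it passed as lower (adjusted p = 0.0336). Pax7 did not change sign and passed in both. Without WT_Cul index 1, Pax7 (−2.70, adjusted p = 0.00118) and Myf5 (1.67, adjusted p = 0.0042) passed, and without WT_Cul index 0 Myog was at −3.77. Of 15 commitment genes 4 rose, with Met, the receptor of hepatocyte growth factor, at 4.30 and Ncam1 at 2.01, and Mef2c fell (−3.00), counts that held adjusted over the list alone (adjusted p = 0.0684 for the list). Of 34 muscle differentiation genes 6 rose, among them Tnnt2 (6.52), Chrna1 (4.74), titin Ttn (4.20) and Neb (4.16), and 2 fell (5 and 1 adjusted over the list alone; adjusted p = 0.105). The mean log2 CPM of this list was 6.38 and 2.32 in WT_Cul (indices 0 and 1) against 3.49 and 2.64 in WT_FI, so that only index 0 was higher as a list, while the risen genes named were higher in both. Of 13 mature myofibre genes 2 rose, including Eno3 (4.04), and 2 fell, including Casq1 (−3.25), by either count (adjusted p = 0.236).

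Among metabolic and stress lists, those of glycolysis, oxidative phosphorylation and p53 targets rose. Of 19 glycolysis genes 6 were higher, among them Ldha (3.12), Pgk1 (3.09) and Pkm2 (2.50), and 2 lower, among them Pfkm (−1.88), and adjusted over the list alone 7 and 2 were (median 0.95, adjusted p = 0.0273). Of 24 oxidative phosphorylation genes Cox5a alone passed (2.51; 0 adjusted over the list alone), and the list rose (median 1.06, adjusted p = 0.00518). Of 16 p53 targets 9 rose, among them Eda2r (2.93) and Mdm2 (2.64), and 2 fell, Perp (−4.71) and Sesn1 (−2.18), with 10 and 3 adjusted over the list alone (median 1.93, adjusted p = 0.0223). The 3 lists had adjusted p = 0.595, 0.705 and 0.422 with an estimated correlation. Tricarboxylic acid cycle and autophagy genes numbered 11 and 15, of which 0 passed by either count (adjusted p = 0.0811 and 0.737 for the lists). Of 22 fatty acid oxidation genes Cpt1b (−2.44) and Ppara (−2.34) fell (0 adjusted over the list alone), with a list median of 0.049, a mean of −0.43 and a test of Down (adjusted p = 0.353). Of 18 sirtuin and NAD genes Cd38 (−4.38) and Qprt (−4.61) fell, 1 adjusted over the list alone (adjusted p = 0.473). Of 10 genes of H4K16 acetyltransferase complexes Wdr5 rose (1.55), also adjusted over the list alone (adjusted p = 0.240). Of 16 NF-kB targets 4 rose, the cytokines Cxcl5 (6.99), Ccl2 (4.14) and Ccl7 (3.46) and the factor Nfkb2 (1.87), and 1 fell, by either count (adjusted p = 0.214). Without WT_FI index 0 or index 1 the calls of Cox5a (adjusted p = 0.0831 and 0.102), Pkm2 (0.103 and 0.142) and Sesn1 (0.0693 and 0.0554) ended, and without index 1 that of Ldha did (0.0717). Without WT_Cul index 0 the calls of glycolysis (0.0627) and oxidative phosphorylation (0.15) ended, and in the other tables' WT libraries that of p53 targets did (0.118).

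Markers of several other cell types were lower in WT_Cul. Of 13 fibroblast genes 9 were lower (11 adjusted over the list alone; median −3.71, adjusted p = 1.31e-05), with Col1a2 at 10235 and 387 CPM (−4.73), Dcn at 2649 and 77.3 CPM (−5.10) and Lum at −5.29. Of 13 endothelial genes 9 were lower by either count (median −2.78, adjusted p = 0.00011), among them Tie1 (−4.06) and Pecam1 (−3.25). Of 8 pericyte genes 6 were lower (7 adjusted over the list alone; median −4.60, adjusted p = 0.000166), among them Rgs5 (−7.26) and Kcnj8 (−6.11). Each had adjusted p = 0.422 with an estimated correlation. Of 4 erythroid genes 3 were lower (4 adjusted over the list alone; adjusted p = 0.022, or adjusted p = 0.574 with an estimated correlation), a call that ended without WT_Cul index 0 (0.0784) or index 1 (0.0659) and in the other tables' WT libraries (0.0994). The haemoglobin genes among them are uncertain because their copies are nearly identical. Leukocyte markers (1 of 14 lower by either count, Lyz2 at −4.57; adjusted p = 0.05), lymphocyte markers (3 of 4 lower, 4 adjusted over the list alone; adjusted p = 0.0684) and Schwann cell markers (among them Mbp −3.60 lower and Ngfr 2.89 higher, by either count; adjusted p = 0.167) did not pass as lists.

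By edgeR, 4200 of 14680 genes passed, 1845 higher and 2355 lower in WT_Cul (6509 at an unadjusted p under 0.05, 734 by chance). Among those with the largest increases were the chromatin protein Hmga2 (0.543 and 148 ± 16.3 CPM; 8.09, SE 0.73, adjusted p = 0.00962), Sct (8.51), Murc (7.77) and Lman1l (7.36). The metalloproteinase Mmp12 was at least 44.2-fold higher, and Ctrb1 (0.0199 and 35.9 ± 49.3 CPM) and the cytokine Csf2 (0.0199 and 8.07 CPM) rose from about 1 fragment. Among those with the largest decreases were Hbb-b1 (at least 86.2-fold lower, and uncertain), Fam196b (81.3), Unc5d (64.5), Ostn (53.1), Glycam1 (46.8) and the channel Hcn4 (46.5), as lower bounds against the floor of 3 fragments per library, bone sialoprotein Ibsp (99.6 and 0.0633 CPM; −10.40) and the red cell anion exchanger Slc4a1 (22.9 and 0.0158 CPM). The count was 2108 without WT_FI index 0, 2063 without WT_FI index 1 and 8050 without WT_Cul index 1. Leaving out either WT_FI library ended the calls of Ctrb1 (adjusted p = 0.326 and 0.379) and Sct (0.121 and 0.137), leaving out either WT_Cul library that of Glycam1 (0.0904 and 0.0648), and without WT_FI index 1 that of Csf2 ended (0.055). In the other tables' WT libraries those of Mmp12 (0.570), Unc5d (0.0540) and Ostn (0.659, log2 0.51) did too. Over all WT libraries that of Ostn also ended (0.103).

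Whether the KO effect differed between states was tested with interaction contrasts over the 14 libraries of the 3 KO tables. By edgeR, 0 of 16698 genes passed for Cul against FI, Diff against FI and Diff against Cul, with 196, 211 and 245 genes at an unadjusted p under 0.05 (835 by chance) and 0 by DESeq2. With the replicate block, Col1a1 (2.91, SE 0.27) and Lmod2 (3.10, SE 0.29) passed for Diff against FI at adjusted p = 0.0349, their KO minus WT difference being higher in Diff.

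Whether KO cells differed along the path that WT cells take was tested with signatures from other libraries. Genes that rise on activation fell in KO_FI (median −0.51, 22 of 146 above 0, adjusted p = 9.68e-09), and genes that decrease on activation fell too (median −0.24, adjusted p = 0.0421). Genes that rise on differentiation rose slightly in KO_FI (median 0.057, 102 of 190 above 0, adjusted p = 0.0421), and those that decrease did not pass (median −0.016, test Up, adjusted p = 0.769). In KO_Diff, genes that rise on activation fell (median −0.081, 71 of 194 above 0, adjusted p = 0.0239) and genes that decrease on activation rose (median 0.53, 38 of 50 above 0, adjusted p = 0.000175). In KO_Cul neither passed (adjusted p = 0.588 and 0.837). The 5 calls had adjusted p = 0.62, 0.919, 0.836, 0.836 and 0.303 with an estimated correlation, in the order given. With signatures of 100 genes the call of genes rising on differentiation in FI ended (adjusted p = 0.999, median −0.0749, 38 of 90 above 0). That of genes rising on activation in Diff ended too (0.0996). Both calls in Diff ended without WT_Diff index 0 (0.846 and 0.853) or KO_Diff index 1 (0.263 and 0.522), and in FI that of genes rising on activation held without each library in turn. The call of genes decreasing on activation in FI ended without WT_FI index 0 (0.0979), WT_FI index 2 (0.291, test Up), KO_FI index 1 (0.418) or KO_FI index 2 (0.225). That of genes rising on differentiation ended without WT_FI index 0 (0.149), WT_FI index 1 (0.456), KO_FI index 0 (0.159) or KO_FI index 1 (0.418).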

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

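Of the tests in this part, that of sex or batch and that of the extent of differentiation in the Diff cultures were chosen only after the result was seen, and that of fibroblasts as a source of collagen transcripts was chosen before it.

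Muscle genes were higher in KO_Diff than in WT_Diff within each index, and the list's test turned without WT_Diff index 0 or KO_Diff index 1, which leaves WT_Diff with the larger share of index 1, where these genes were far higher. A property that both libraries of an index share would not by itself give a difference within an index. Sex is not shown to be such a property. The libraries of index 0 held Xist and also the Y chromosome gene Ddx3y (28.1 CPM in WT and 24.0 CPM in KO). For index 1, Ddx3y was at 39.9 (WT) and 80.3 (KO) CPM, while the Y chromosome gene Eif2s3y was at 48.0 and 55.3 CPM. A sex make-up that differs between genotypes within an index therefore stays open. The medians within an index were 1.24 for index 0 and 1.00 for index 1 (SE over genes 0.12 and 0.116). In both, 33 of 34 genes, Myh3, Ckm and Acta1 among them, were higher in KO. Genes are not replicates, and each median compares 1 library per genotype. The medians therefore cannot set a cause that differs between single dishes apart from genotype. Fibroblasts in the KO_Diff cultures stay open as the source of the higher Col1a1 and Col1a2. The other 10 fibroblast markers had medians of 0.726 for index 0 and −0.273 for index 1 (SE over genes 0.142 and 0.161). The bound set beforehand, at or below 0 within either index, wrongly let 1 library per genotype decide. What also stays open is that dishes may have differed in how far they had differentiated for reasons other than genotype, since the list differed by 6.47 between the 2 WT_Diff libraries, more than between genotypes, and with 1 library per genotype and index this cannot be told apart from the KO. A faster entry of KO cells into differentiation is a biological explanation that also stays open as a hypothesis.

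Single libraries stood apart from their group in 3 of 64 tests, where chance gives about 1 in 20. The list of p53 targets was at 4.94 mean log2 CPM in WT_FI index 0 of the FI table and at 4.73 to 4.78 in the other 4 WT_FI libraries, a gap of 0.768 of the whole range. Fatty acid oxidation genes were at 5.54 in WT_Cul index 0 of the table of WT states and at 5.08 to 5.13 in the other 3 (0.887 of the range). Myod1 was at a log2 CPM of 9.36 in WT_Cul index 1 of the table of WT states and at 11.1 to 11.3 in the other 3 (0.913 of the range). These levels are set across tables that were processed separately.

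The KO effect on a list differed between states by camera on the interaction contrasts in 11 of 78 tests, with the median difference in log2 given here. For Cul against FI the KO minus WT difference was higher in Cul for fibroblast genes (1.19, adjusted p = 0.0243), G2/M genes (0.811, adjusted p = 0.00957), immediate early genes (0.651, adjusted p = 0.00116) and oxidative phosphorylation (0.346, adjusted p = 0.04). For Diff against FI it was higher in Diff for pericyte markers (2.08, adjusted p = 0.0165), muscle differentiation genes (1.5, adjusted p = 0.04), G2/M genes (0.952, adjusted p = 0.0238), the Notch pathway (0.747, adjusted p = 0.00221), myogenic commitment (0.70, adjusted p = 0.0238) and immediate early genes (0.531, adjusted p = 0.00572). For Diff against Cul it was higher in Diff for endothelial markers (0.82, adjusted p = 0.04). None of the 11 passed with the correlation estimated from the data, the lowest being adjusted p = 0.91 with an estimated correlation.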

How the results depend on the processing

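The replicate block by table index, the fits without the FI libraries of index 0 and over the other tables' WT libraries, and all tests with these settings were chosen only after the results were seen, and the other alternatives were planned. For single genes, lists and signatures, 1813 planned values kept their direction and their side of the threshold, 127 lost a call, 33 gained a call and 41 turned; of the added ones 455 were kept, 14 lost, 109 gained and 4 turned. Of counts per comparison, 85 planned and 11 added ones were within 1.5 times of the main count, and 30 and 11 were not. Unless a cause is named here, the cause was not tested. Depth ranged from 24254119 to 82825550 fragments per library, and libraries of a group differed by far more than counting error. In simulated FI counts without pair effects (14943 genes), 12.7% of 2-fold changes were recovered. Depth was not varied in the simulations, so its part in this was not tested. RLE size factors left each count of genes and lists within 1.5 times.

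In FI, where edgeR called 0 genes, DESeq2 called 117 (67 higher, 50 lower), limma on log2(FPKM + 0.1) 2 (both lower), limma with a minimum FPKM of 1 called 1 (lower), the fit over all 18 libraries 1 (lower) and the fit without the index 0 libraries 1 (lower). In Cul, also 0 by edgeR, DESeq2 called 3 (all lower) and limma with a minimum FPKM of 1 called 5 (1 higher, 4 lower). For the WT states, 4200 by edgeR, the counts were 5763 by DESeq2, 4193 with RLE, 4511 without a filter, 3627 by limma on log2(FPKM + 1), 6780 over 18 libraries, 7885 over all WT libraries (3795 and 4090; 3763 shared) and 9401 over the other tables' WT libraries (4306 and 5095), of which 3729 were shared and 3712 had the same direction. Leaving out libraries gave 2063 (without WT_FI index 1; 389 higher and 1674 lower) to 8050 (without WT_Cul index 1; 3909 and 4141), and 2108 without WT_FI index 0. Over all WT libraries Sirt1 was at 0.14 and Myf5 at −0.49, and over the other tables' Sirt1 was at 0.47, Ostn at 0.51, Myf5 at −1.11 and Myog at −3.86.

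The planned block by the labels' replicate number could not be run, because the tables carry only an index. With the table index as a replicate block, edgeR called 3 genes in FI (all lower) and DESeq2 255 (95 higher, 160 lower), and the FI lists numbered 8. In Cul, Diff and the WT states the libraries share only an index, with correlations of deviations of 0.732, 0.787 and 0.387 between libraries of the same index. There the block gave 3 genes in Cul (Col1a2 1.92 and H19 1.54 higher, Elovl4 −1.95 lower; DESeq2 390, 72 higher and 318 lower), 147 in Diff (131 higher, 16 lower; DESeq2 99, 90 and 9) and 6176 for the WT states (DESeq2 6416), with 4183 of the 4200 shared, and limma on log2(FPKM + 1) gave 0 in the 3 KO comparisons and 4705. The genes with the largest changes among the 147 were Pisd-ps1 (3.71, uncertain as a pseudogene), Col1a1 (2.75), Capn3 (2.69), Cdkn1c (2.52), Myh3 (2.52), Myh7 (2.50), Col1a2 (2.42) and Cmya5 (2.31), and lower Adh1 (−2.44), Elovl4 (−1.77), Gsta1 (−1.49), Nrxn2 (−1.44), P2rx7 (−1.32), Slpi (−1.32), Cd34 (−1.29) and Ptgr1 (−1.18). Of the 34 muscle genes 20 passed in that fit, and 30 adjusted over the list alone. In simulated counts with pair effects, the block in Diff recovered 23.4% of 2-fold and 93.5% of 4-fold changes with 7.44% of its calls false (14281 genes), or 65.7% and 100% with 29.1% false where the spread was that of the FI pairs (14350 genes). In Cul it recovered 86.3% and 98% with 10.2% false (13768 genes), or 51% and 94.9% with 13.7% false (13829 genes). The interaction contrasts gave 2 genes. The block gave 2 lists in Cul, 10 in Diff and 17 for the WT states, and signatures that passed numbered 5. It changed no other reported FI call.

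Lists that passed numbered 5 in FI, 3 in Cul, 7 in Diff and 14 for the WT states. With an estimated correlation 0 passed in each, and by fry 0 in FI, Cul and Diff and 10 for the WT states. Leaving out libraries gave 4 (without WT_FI index 1) to 10 (without KO_FI index 2) in FI, 4 to 8 in Cul (8 without WT_Cul index 0 or KO_Cul index 0) and 5 to 14 in Diff (14 without WT_Diff index 1, 13 without KO_Diff index 1, 11 without KO_Diff index 0, 5 without WT_Diff index 0). Signatures that passed numbered 5, with 100 genes 3, with an estimated correlation 0, and without a library 1 (WT_Diff index 0 or KO_Diff index 1) to 6; without WT_FI index 0 or KO_FI index 1 they numbered 3. With 100 genes, the genes that decrease on activation had adjusted p = 0.895 in Cul (Down, with a median of 0.165).

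Leaving out a library turned these log2 changes. In FI, Myog ranged from −1.62 to 0.64 (turned without WT_FI index 1). In Cul, Myod1 ranged from −0.15 to 0.24 and Myog from −2.94 to 4.09 (lowest without KO_Cul index 0). In Diff, without WT_Diff index 0 the highest values were 0.33 for Sirt1 (lowest −0.57), 0.48 for P2rx7 (−3.13), 0.93 for Cd34 (−3.62) and 0.49 for Pax7 (−0.56), and Myod1 was lowest at −0.38 (highest 0.73). Without KO_Diff index 1 the lowest values were −4.05 for Capn3 (highest 9.16), −0.018 for Cdkn1c (4.84), −5.96 for Myh3 (11.02), −3.44 for Myh7 (8.39), −1.57 for Cmya5 (5.86), −2.74 for Myog (4.94), −0.21 for Mef2d (1.24) and −1.25 for Neb (4.20). Without KO_Diff index 0, Pisd-ps1 was lowest at −2.31 (highest 8.0) and Myf5 highest at 0.052 (lowest −0.12). For the WT states, Sirt1 ranged from −0.52 to 0.13 (without WT_FI index 1) and Myog from −3.77 (without WT_Cul index 0) to 4.93.

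The adjusted p of lists and signatures whose direction turned when a library was left out ranged as follows. For myogenic commitment in Diff it was 0.00119 to 0.776, and for muscle differentiation in Diff 3.2e-21 (Up) to 0.0252 (Down, without WT_Diff index 0; Down also at 5.02e-08 without KO_Diff index 1). For genes that decrease on activation it was 1.57e-06 to 0.418 in FI and 0.0608 to 0.85 in Cul (Down, without WT_Cul index 0), and for genes that decrease on differentiation 0.149 to 0.89 in FI. For genes that rise on activation it was 2.16e-05 (Up, without WT_Cul index 0) to 0.00345 (Down, without KO_Cul index 0) in Cul and 0.000104 to 0.846 in Diff.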

Other observations

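The fit of a KO effect common to the 3 states, and the tests of the WT libraries between tables, were chosen only after the results were seen, while those of sign flips, linkage and other splits were chosen before their results.

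Over the 7 pairs of libraries with the same index in the 3 KO tables, a joint edgeR fit with a block for each pair called 27 of 16698 genes (14 lower and 13 higher in KO, adjusted p from 0.0340 to 0.0499; 1264 at an unadjusted p under 0.05). Of these, 26 had the same sign in all 7 pairs, and Dcx in 6. The fit over the same pairs favours such genes, so this is no separate support. Kcne4 differed by only −0.157 in the Cul pair of index 0, from 14 (WT) and 11 (KO) fragments. Elovl4, which elongates very long chain fatty acids, was lower in all 3 states (−2.36, SE 0.25), as were the potassium channel subunit Kcne4 (−2.08), the matrix proteoglycan Spock1 (−2.01), Rhoh (−1.83), Adh1 (−1.60), Slc24a2 (−1.48), the neuronal protease inhibitor Serpini1 (−1.29), Tmem229a (−1.22), Calcrl (−1.03), the calcium channel Cacna1d (−0.99), the G protein regulator Rgs2 (−0.81), Ankrd29 (−0.70), Pir (−0.66) and Zfp783 (−0.61). Higher were Dcx (3.27), Ms4a4d (1.76), D630003M21Rik (1.38), the peptidase Ace (1.29), the metalloproteinase Mmp19 (1.18), Fndc1 (1.13), the kinase Ikbke (1.13), Apol6 (0.94), Gm14492 (0.94), Syn2 (0.94), Lsp1 (0.85), the thioesterase Acot11 (0.78) and Prss57 (0.69). Across 13259 genes, which are not independent replicates, the KO effects had Pearson's r of 0.0623 between FI and Cul, 0.138 between FI and Diff and 0.125 between Cul and Diff (Spearman's rho −0.0339, 0.202 and −0.0808).

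The 27 genes may form a KO effect shared by the states, as a hypothesis. The pairing in Cul and Diff rests only on a shared index, and in FI it is not shown for indices 1 and 2. Of the 64 ways to flip the sign of the pairs, 1, the real assignment, gave as many genes, and the highest other gave 1. That share of 1 in 64 lies under 0.05 only if the pairs are taken as real and independent. Since the pairing is not shown and the fit was chosen after the results were seen, chance is not excluded. Variants from another strain carried within 100 genes of Sirt1 or Pax7 in gene order are argued against as a source of most of the 27 genes. Of these, 26 could be placed, and 1 (Prss57, near Sirt1) lies within that range, where 0.65 would be expected among 402 measured neighbours. Longer carried segments and differences of strain elsewhere in the genome were not tested. The count rests on single pairs: without FI index 1, Cul index 1 or Diff index 0 it was 0, without FI index 2 it was 1, without Cul index 0 it was 2, without FI index 0 it was 4, and without Diff index 1 it was 67. Direct repression by SIRT1 was not tested.

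The WT_FI libraries of the table of WT states differed from those of the FI table, with lower Pax7 (log2 −2.77), Myf5 (−2.14), Calcr (−1.54) and Cd34 (−1.19) and higher Col1a1 (3.11), Pdgfra (2.19) and Dcn (2.17), over tables processed separately. A lower share of satellite cells with a rise of all other cell types together was not seen in the list medians. It is not excluded, since the clear fall of leukocyte markers rests on 1 library. Leukocyte markers were lower (median −1.81, SE 0.224 over genes), mainly in index 1. Their mean log2 CPM was 2.80 and 0.674 for indices 0 and 1, against 2.92 to 4.32 in the FI table. Endothelial markers were nearly level (median 0.022), while fibroblast (1.95, SE 0.397), Schwann (1.54) and pericyte (1.46) markers were higher. The gap between the fibroblast and leukocyte lists was wider in both libraries (6.17 and 7.73, against 2.90 to 4.58). The difference was 3.26, with an SE over libraries of 0.92. Higher fibroblast markers alone would widen this gap, so it does not show that leukocyte markers failed to rise. A lower share of satellite cells with an uneven change of the other cell types stays open. Fibroblasts in the WT_FI libraries of the table of WT states may be part of the difference, since their list median was 1.95. Col3a1, an abundant fibroblast transcript, was higher by only 0.73, so this stays open. Markers of other cell types were present in these sorted libraries, with Pdgfra at 162 and 84.9 CPM and Pecam1 at 86.6 and 89.7 CPM (indices 0 and 1). FACS isolation is therefore no argument against fibroblasts here. Counting that differs between the tables also stays open, since Pax7 was lower by a log2 ratio of −1.71 between the WT_Cul libraries of the tables as well, where quiescence genes had a median of 0.877 against −1.24 in FI. Between these WT_Cul libraries, markers of all 5 other cell types were higher in the table of WT states. The medians were 3.81 for fibroblast, 2.83 for endothelial, 2.21 for leukocyte, 4.95 for pericyte and 5.1 for Schwann markers. Higher markers of other cell types were therefore not particular to the WT_FI libraries of that table. No biological explanation was tested, as the labels give these libraries the same group.

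With 6 FI libraries there are 10 splits of 3 against 3, too few for a share under 0.05. For edgeR, the real split gave 0 genes and the highest other 0, so 10 of 10 gave as many. For DESeq2, the real split gave 117 genes and 3 of 10 splits gave as many, the highest other, 1129, setting WT_FI indices 0 and 2 with KO_FI index 0 against the rest, which points to a structure of the samples other than genotype. The other splits that part all 3 pairs gave 1, 0 and 2 genes by DESeq2. For lists, the real split gave 5 and 9 of 10 gave as many, the highest other giving 11 and the other splits that part all pairs 6, 5 and 8. Over the 5 WT_FI and 4 WT_Cul libraries, 1 of 100 splits drawn from the 126 possible, the real one with 7885 genes, gave as many (highest other 3158). That is a share under 0.05, with the libraries taken as independent, which the labels do not show.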
